A study of Homo sapiens with 6 samples.

How the data were processed

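Total RNA of 3 proliferating human leukaemia cell lines, K562, UT7-5.3 and MV4-11, was measured on 6 arrays. Each line had been transduced with a lentiviral vector carrying an shRNA against CXXC5 (shRINF) or a control sequence (shcontrol). Per the labels' protocols, RNA was extracted with Trizol and a column kit, reverse transcribed, amplified by in vitro transcription, and turned into fragmented, biotin-labelled single-stranded DNA with a whole-transcript kit. The labels give neither the shRNA sequences nor the time after transduction.

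The deposited values are log2 expression values per feature (transcript cluster), made by the authors with RMA in Affymetrix Expression Console, per the submitters' processing notes. The versions and the genome build are not given in the sources used here. RMA corrects background, brings all arrays to a common distribution of probe values and summarises the probes of a feature, so that a change shared by most transcripts would be removed. The log base is not stated in the labels and was taken as 2 from the method and from the range of values, 1.63 to 13.89. Values are rounded to 2 decimals and were not centred by gene. The file holds all 67528 features with no detection calls, so a low value cannot be told from background, and values near 4 or below were read as close to the floor. Arrays give no counts, and the number of arrays limits the precision.

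Features were named with the platform's annotation table, in which 23781 had 1 gene symbol, 1543 had several and 42204 had none listed. Features with several or no symbols were not named and were left out of the gene comparisons. A gene was kept where a feature was at log2 5 or more on at least 2 of 6 arrays, and the feature with the highest mean stood for a gene with several. This kept 15330 genes. Of these, 15169 (98.9%) matched a RefSeq gene table of assembly GRCh38.p14, which supplied gene type, length and chromosome, and 12845 were protein coding. No coordinates are given because the build of the array annotation is not named.

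The labels give no replicate numbers. The arrays were paired by cell line, since each line gave 1 array of each group. The pairing was plain in the values, as arrays of a line correlated at 0.993 or more and arrays of different lines at 0.959 or less. Differences were tested with limma 3.58.1 (lmFit and eBayes, R 4.3.3) with the cell line as a block, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The fit had 2 residual degrees of freedom and 10.7 prior degrees of freedom. The p-values rest on 3 lines with 1 array per condition, and no line had a second culture. An exact sign-flip test of 3 pairs cannot give a two-sided p below 0.25. Within a line, differences are given without a test. Gene lists, fixed with the design before the data were examined, were tested with camera at a preset correlation of 0.01 and with an estimated one, and with fry, which asks whether the genes of a list move one way on balance and does not compare the list with other genes. For each line, the median of a list was set against 10000 random lists of the same size, drawn from 20 bins of mean level. Lines were compared pairwise in the additive fit of cell line and shRNA, at 2-fold or more and an adjusted p under 0.05.

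The rule for named genes was set in advance. It took CXXC5 and SMAD7, up to 10 genes higher and 10 lower past the threshold with the same sign in 3 lines, filled up where fewer passed by genes of the same sign with the largest smallest difference, 5 genes per line and direction, up to 4 genes per list by mean difference, and 4 genes per lineage list by range between lines. Other genes, among them MPO, ELANE, LYZ, JUN, MARCKS, SELENOP, MT1G in MV4-11 and RNASE6, were named after their values were seen.

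The procedures were tested on simulated data of 15330 genes with the spread of the real fit and 200 changed genes, in 10 runs. For the comparison across lines, 78.8% of genes changed by 0.5 log2 units were recovered, and 100% of those changed by 1 or by 2, with 9.9 false calls per run. Each changed gene had the same shift, and noise of the same size, in all 3 lines. In the real data the SD of the differences over genes was 0.103 in K562, 0.259 in UT7-5.3 and 0.179 in MV4-11. These rates therefore do not carry over to genes whose difference varies between lines. For gene lists, 100% of lists shifted by 0.2 were recovered with no false call, and for line differences 100% of genes changed by 2. The noise was drawn independently for each gene, and a shifted cell cycle list was tested with camera at the preset correlation alone. The real lists had estimated correlations of up to 0.586, so the list result does not carry over to them. Alternatives covered the filter, the feature chosen for a gene, 3 further normalizations, the variance model, the block, the threshold, the fold minimum and leaving out each line. After the data were examined, 2 were added, removing a trend with mean level, gene length and chromosome in each line, and using protein-coding genes alone. Figures were drawn with matplotlib 3.10.9.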

Results

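Expression was measured on 6 whole-transcript arrays of proliferating human leukaemia cell lines that had been transduced with a lentiviral vector. Each line gave 1 array with an shRNA against CXXC5 (shRINF) and 1 array with a control shRNA (shcontrol), so that each group held 3 arrays and the cell line was the replicate. CXXC5, also called RINF, is a nuclear protein with a CXXC zinc finger that binds CpG-rich DNA. K562 is a line from chronic myeloid leukaemia with erythroid features, UT7-5.3 derives from the cytokine-dependent UT-7 megakaryoblastic line, and MV4-11 comes from an acute leukaemia with monocytic features. Each array held 67528 features, with a median log2 value between 4.64 and 4.71. Across all features, the arrays of a line correlated at 0.997 in K562, 0.993 in UT7-5.3 and 0.996 in MV4-11, and arrays of different lines at 0.930 to 0.959. These are correlations across features, which are not independent replicates. After the filter on low values 15330 named genes were compared.

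The first question was whether the targeted transcript was lower with its shRNA. CXXC5 was lower in all 3 lines, by -0.58 ± 0.11 log2 units (mean ± SD of the 3 within-line differences, n = 3). In K562 it went from 8.40 to 7.95, or 73.2% of the control level. In UT7-5.3 it went from 8.42 to 7.76, or 63.3%, and in MV4-11 from 8.58 to 7.95, or 64.6%. The 95% confidence interval from limma, not adjusted for the number of genes, was -0.77 to -0.39. Adjusted over all 15330 genes by the Benjamini-Hochberg method, limma's p for CXXC5 was 0.153, above the threshold of 0.05. Without MV4-11 limma's adjusted p was 0.0208, in a fit that gave all genes the same pooled spread. The range over 14 alternatives was 0.0208 to 1. SMAD7, an inhibitor of TGF-beta signalling linked to CXXC5 in published work on this protein, had values of -0.14 in K562, -0.06 in UT7-5.3 and -0.22 in MV4-11. Its mean was -0.14 ± 0.08 (SD, n = 3; limma adjusted p = 0.771).

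**Figure D1:**
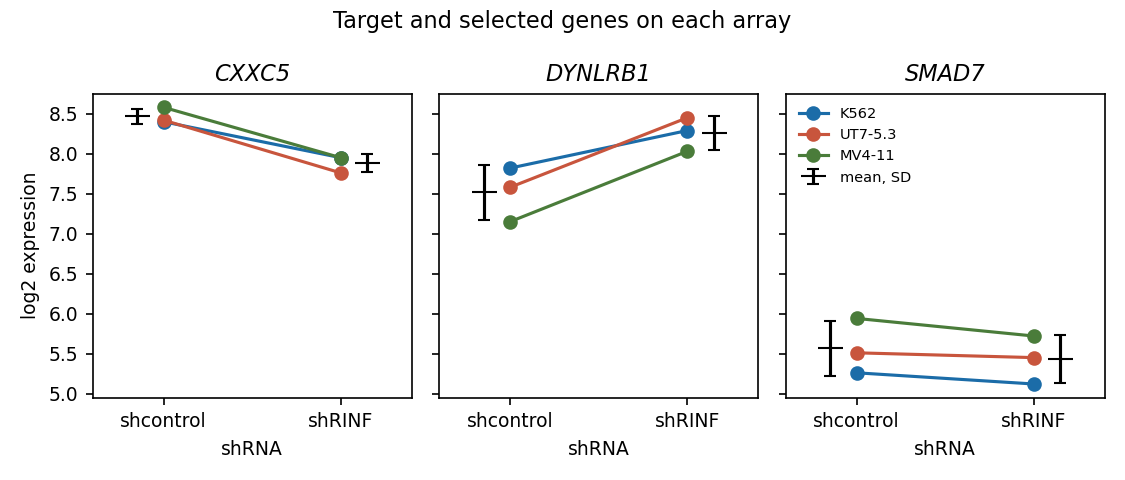
Log2 expression of CXXC5, DYNLRB1 and SMAD7 on the y axis under each shRNA, with a line joining the arrays of a cell line and black bars for the mean and SD of the 3 lines. CXXC5 was lower with shRINF in each line, by 0.58 on average (log2 change -0.58), and DYNLRB1 was higher by 0.47 to 0.88.

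The comparison of shRINF with shcontrol across the 3 lines asked which transcripts moved the same way in all of them. No gene passed the threshold of 0.05 in either direction, and CXXC5 and DYNLRB1 had the lowest p-values. DYNLRB1, a light chain of the cytoplasmic dynein motor, was higher by 0.47 in K562, 0.87 in UT7-5.3 and 0.88 in MV4-11. Its mean difference was 0.74 ± 0.23 (SD, n = 3), with a limma adjusted p of 0.0899, the smallest of all genes. Without MV4-11 limma's adjusted p was 6.27e-04, in the same fit of pooled spread, against a range of 6.27e-04 to 1 over 14 alternatives. DYNLRB1 differed more than CXXC5 itself, and whether its difference came from the sequence of either shRNA and not from the loss of CXXC5 was not tested. Of the genes that did not pass but were higher in each line, the next by smallest difference were H2AX, the histone variant phosphorylated at DNA breaks, at 0.42 ± 0.04, the small nucleolar RNA SNORD114-3 at 0.48 ± 0.16, and the histone gene H2BC3 at 0.55 ± 0.19 (SD, n = 3). SNORD114-3 lay near the floor of the array in K562 and MV4-11, at 2.48 and 2.46 in the controls. DNAJC3-DT, RNA5SP141, IRAG2, CD69, ZNF35 and RNA5SP429 followed, with mean differences between 0.29 and 0.40. CD69 is an early activation antigen of leukocytes, and lay near the floor in the MV4-11 control, at 3.43, as did H2BC3 at 3.80.

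Besides CXXC5, 9 genes lower in each line were named by the same rule, none of which passed. The microRNA gene features MIR4288, MIR3650 and MIR551B had mean differences of -0.45 ± 0.13, -0.35 ± 0.05 and -0.34 ± 0.03 (SD, n = 3). GNG8, SBK1, TRBV11-2, POM121L12, MAFA and MIR33B followed, with mean differences between -0.35 and -0.28. Their control values lay between 4.99 (TRBV11-2 in UT7-5.3) and 7.36 (MIR33B in MV4-11).

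By limma, 981 of 15330 genes had an unadjusted p under 0.05, 656 higher and 325 lower with shRINF, where 766.5 would be met by chance. The differences had the same sign in all 3 lines in 28.9% of genes, against 25% by chance. Without MV4-11, which leaves K562 and UT7-5.3, limma called 41 genes higher and 11 lower. That fit has 1 residual degree of freedom, and its spread came from the pooled prior, whose degrees of freedom were estimated as infinite. All genes thus had the same spread. A gene passed by the size of its mean difference, whether or not K562 and UT7-5.3 were alike. Among those called were HBD, DYNLRB1 and EPSTI1 on the higher side and CXXC5 on the lower side. In MV4-11, 21 of the 41 and 8 of the 11 had the same sign. Several SNORD113 and SNORD114 features, which are alike in sequence, were among the higher. Others rested on UT7-5.3 alone, such as NTS (-0.03 in K562 and 1.46 in UT7-5.3) and POLR2A (0.03 and -1.03). The counts therefore do not show that K562 and UT7-5.3 agreed.

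Gene lists chosen before the data were examined asked whether functional groups moved together. With camera at its preset correlation, 4 of 19 lists shifted upward and 4 downward, at an adjusted p under 0.05. With an estimated correlation none of the 19 passed (smallest adjusted p = 0.571), nor did any with fry (smallest adjusted p = 0.547). Both of these tests rest on the 2 residual degrees of freedom of the fit, so that they could hardly pass over 19 lists. For cholesterol synthesis and uptake the estimated correlation was 0.0320, yet camera's unadjusted p was 0.0912 with it, against 3.73e-04 at the preset. These tests therefore do not bear the preset calls out, and for cholesterol they do not show that correlation accounts for the call. The other called lists had higher estimates, at 0.423 for retinoid response, 0.412 for histones, 0.357 for lymphoid markers and 0.132 for cell cycle. They were 0.0829 for immediate early, 0.0613 for granulocytic and monocytic and 0.0539 for interferon genes. There the parts played by correlation and by the few degrees of freedom were not separated. No list member passed the threshold over all genes.

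Replication-dependent histone genes, which encode the core and linker histones made in S phase, had the highest mean difference of the 19 lists, 0.22 over the 8 of 31 members measured. All 8 were higher in UT7-5.3 and in MV4-11, and 5 were higher in all 3 lines. Against random lists matched on mean level, their median lay at percentile 98.0 in K562, 98.9 in UT7-5.3 and 100 in MV4-11. Each is a rank among the genes of a single pair of arrays and not a test. H1-5 was higher by 0.33 ± 0.12, H2AC6 by 0.31 ± 0.28, H2BC5 by 0.30 ± 0.10 and H2BC21 by 0.27 ± 0.06 (SD, n = 3). These 4 had an adjusted p under 0.05 when adjusted over the list alone, the smallest being 0.0190 by limma. Camera gave the list an adjusted p of 5.16e-06, and 0.571 with an estimated correlation.

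Genes of cholesterol synthesis and uptake had a mean difference of 0.10 over 19 genes, of which 7 were higher in all 3 lines and none lower in all 3. HMGCS1, an early enzyme of the mevalonate pathway, was higher by 0.33 ± 0.18 and INSIG1, a sterol-sensing regulator, by 0.23 ± 0.27 (SD, n = 3). CYP51A1 and STARD4 were each higher by 0.19. Cell cycle genes had a mean difference of 0.09 over 32 genes, with 11 higher in all 3 lines and none lower in all 3. The mitotic kinase AURKA was higher by 0.26 ± 0.15, the phosphatase CDC25C by 0.20 ± 0.08, CDK1 by 0.20 ± 0.18 and the replication licensing factor CDC6 by 0.19 ± 0.12 (SD, n = 3). In MV4-11, 28 of the 32 were higher, against 20 in UT7-5.3 and 21 in K562. Ranked against random lists matched on mean level, the median of the cell cycle list lay at percentile 42.9 in K562, 23.3 in UT7-5.3 and 100 in MV4-11, the cholesterol list at 77.1, 71.8 and 99.8, and the interferon list at 30.7, 99.5 and 100. In K562 and UT7-5.3 the cell cycle list was thus no higher than genes of like mean level over the 6 arrays. Interferon response genes had a mean difference of 0.10 over 15 genes, with 2 higher and 2 lower in all 3 lines, and in K562 5 were higher and 8 lower. The transcription factor IRF7 and the exonuclease ISG20, lower in each line, had mean differences of -0.11 and -0.12. HERC5 was higher by 0.60 in UT7-5.3 and 0.55 in MV4-11, and lay near the floor in K562, at 3.85 in the control. IFIH1, a sensor of double-stranded RNA, was higher by 0.81 in UT7-5.3 and 0.21 in MV4-11, and USP18 by 0.34 and 0.40. IFI44 was higher by 0.63 in UT7-5.3 and lay near the floor in K562 and MV4-11, at 2.88 and 3.18 in the controls, so that its differences of 0.06 and -0.15 there say little. Camera's adjusted p was 0.00177 for the cholesterol list, 2.27e-04 for cell cycle and 0.0286 for interferon response, and each was 0.571 with an estimated correlation. No member of the 3 lists passed when adjusted over the list alone. Without MV4-11 the preset call ended for cholesterol (adjusted p = 0.145, range over 12 alternatives 8.51e-05 to 0.571), cell cycle (0.130, range 9.36e-06 to 0.571) and interferon response (0.145, range 0.00295 to 0.737). Without UT7-5.3 it ended for interferon response (0.737). The interferon call also ended with no filter (0.120), a filter at log2 6 (0.227) and median centring (0.0505), and the cell cycle call with cyclic loess (0.0590). The interferon mean was 0.06, 0.09 and 0.10 in those settings, and the cell cycle mean 0.05 after cyclic loess.

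Granulocytic and monocytic genes had a mean difference of -0.09 (median -0.13) over 27 genes, of which 9 were lower in all 3 lines. Against random lists matched on mean level, their median lay at percentile 0.03 in K562, 0.245 in UT7-5.3 and 0 in MV4-11. These too are ranks and not a test. Mean level was taken over the 6 arrays and not within a line. Members such as CTSG, at 5.47 in K562 and 11.31 in MV4-11, were thus matched to genes mostly of higher level in K562. In UT7-5.3, where the differences varied with mean level, a low rank may in part follow from this. The list passed at camera's preset correlation (adjusted p = 0.00124) but not with an estimated correlation (adjusted p = 0.571) or with fry (0.547). The integrin gene ITGAM was lower by -0.06 in K562, -0.46 in UT7-5.3 and -0.70 in MV4-11. In MV4-11 the members went both ways. The neutrophil granule proteases CTSG and ELANE were higher there by 1.22 and 1.09, and myeloperoxidase (MPO) by 0.87. The nuclear antigen MNDA was higher by 0.91, whereas S100A9 was lower by -1.06 and the lysozyme gene LYZ by -0.84. Immediate early genes had a mean difference of -0.09 over 26 genes, with 7 lower in all 3 lines. EGR1 was lower by -0.14 in K562, -0.31 in UT7-5.3 and -1.02 in MV4-11, IER3 by -0.66 in UT7-5.3, and FOS by -0.55 in MV4-11. PHLDA1 was lower by -0.19 ± 0.10 (SD, n = 3), while JUN was higher by 0.18 ± 0.10. Retinoid response genes had a mean difference of -0.12 over 14 genes, all 14 lower in UT7-5.3. DHRS9, a retinol dehydrogenase, was lower by -1.28 in MV4-11, and the integrin gene ITGB2 by -0.36 in UT7-5.3. CRABP2 and CD38 had mean differences of -0.17 and -0.14. Lymphoid markers had a mean difference of -0.08 over 15 genes, 14 of them lower in UT7-5.3, and IL7R was lower by -1.17 in MV4-11. CD7 and CD79A had mean differences of -0.17 and -0.15, and CD3D of 0.14. In UT7-5.3 genes of low mean level were lower in general (medians of -0.14 to -0.16 in bins 2 to 4 of 10), and 10 of 11 fibroblast and epithelial markers were lower too, with a median of -0.22 against -0.22 for the retinoid and -0.23 for the lymphoid list. Against random lists matched on mean level the retinoid and lymphoid medians there lay at percentiles 2.20 and 1.01. The fibroblast and epithelial list lay at 1.85 there and the CXXC and DNA methylation list at 1.07. Such ranks were thus not particular to the retinoid and lymphoid lists. In K562 the retinoid and lymphoid medians lay at 14.3 and 2.21, and in MV4-11 at 46.9 and 64.3. Each is a rank among the genes of 1 pair of arrays and not a test. Camera's adjusted p was 0.00287 for immediate early genes, 0.00225 for retinoid response and 0.0286 for lymphoid markers. With an estimated correlation these were an adjusted p of 0.571, 0.721 and 0.815. No member of the 4 lists passed when adjusted over the list alone. Without UT7-5.3 the preset call ended for the retinoid list (adjusted p = 0.309, range over 12 alternatives 0.00155 to 0.721) and the lymphoid list (0.309, range 0.0237 to 0.815), and without K562 for the lymphoid list (0.0907). The lymphoid mean was -0.04 without UT7-5.3 and -0.10 without K562, and the retinoid mean -0.07 without UT7-5.3. The lymphoid call held in 4 of 12 alternatives, and also ended with no filter (0.0782), a filter at log2 6 (0.215), quantile normalization (0.176), cyclic loess (0.215) and the trend with mean level, gene length and chromosome removed (0.185), an alternative added after the data were examined. In the list Retinoid response the call held with that trend removed (adjusted p = 0.00495).

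Erythroid genes had a mean difference of 0.06 over 30 genes and did not pass (camera adjusted p = 0.115; 0.721 with an estimated correlation). Adjusted over the list alone, 3 members passed by limma, each at an adjusted p of 0.0462. They were HBD, the delta-globin gene, with 0.65 in K562, 1.32 in UT7-5.3 and -0.05 in MV4-11, AHSP, the alpha-globin chaperone, with 0.30, 0.59 and 0.18, and CPOX, a haem synthesis enzyme, with -0.50, -0.52 and -0.05. HBD and AHSP lay near the floor in the MV4-11 control, at 3.91 and 3.45, so that their values there say little. The carbonic anhydrase gene CA1 was higher by 0.16 in K562 and 0.77 in UT7-5.3. In K562, 25 of the 30 were higher, with a median of 0.07 (percentile 99.9 of random lists of the same size matched on mean level). In UT7-5.3, 17 were higher and 13 lower (percentile 83.7), and in MV4-11, 10 were higher and 19 lower (percentile 3.05). These percentiles rank the list among the genes of 1 pair of arrays, genes that are not independent, and are no test of a difference in a line. Mean level was taken over the 6 arrays and not within a line. RHAG, for one, lay at 11.47 in K562 and 4.32 in MV4-11. Without MV4-11, the line with the lowest levels of RHAG, HBZ and GATA1, the list passed with camera's preset correlation (adjusted p = 0.00677, against a range of 0.00677 to 0.721 over 12 alternatives). The estimated correlation, which gave the 0.721, was run with all 3 lines and not without MV4-11.

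The TGF-beta and BMP list had a mean difference of 0.01 over 30 genes (camera adjusted p = 0.890; 0.902 with an estimated correlation). SMAD4 was higher by 0.27 ± 0.24, ID1 by 0.25 ± 0.26, ID2 by 0.22 ± 0.17 and BAMBI by 0.18 ± 0.17 (SD, n = 3), none of them past the threshold. This list holds SMAD7, which the published work on RINF had already named, so it was not chosen independently of that work. The other 9 lists did not pass either, and their mean differences lay between -0.04 and 0.04. In the Wnt list FZD6 was higher by 0.30 ± 0.26, and FZD7, NKD1 and LRP6 had mean differences of -0.17, -0.14 and 0.13. Among megakaryocytic genes ITGB3 and ITGA2B, the chains of the platelet fibrinogen receptor, were lower in UT7-5.3 by -0.86 and -0.58, while TUBB1 was higher by 0.52 in K562 and 0.54 in UT7-5.3 and lower by -0.38 in MV4-11. RAB27B was higher by 0.32 in K562 and 0.60 in UT7-5.3. Among progenitor genes CD34 was lower by -0.55 in UT7-5.3, KIT was higher by 0.59 in MV4-11, and MEIS1 had a mean difference of 0.19. The stress response gene DDIT3 was higher by 0.33 ± 0.21 (SD, n = 3) and the cystine transporter SLC7A11 by 0.78 in UT7-5.3. EDEM1 and SEL1L of that list had mean differences of -0.19 and 0.18. The stress response list did not pass with all 3 lines (camera adjusted p = 0.228; 0.827 with an estimated correlation), but did at the preset correlation without UT7-5.3 (0.0310, range over 12 alternatives 0.0310 to 0.962). Among p53 targets ZMAT3 had a mean difference of -0.23 ± 0.16, PHLDA3 of -0.18 ± 0.03, SESN2 of -0.17 ± 0.18 and MDM2 of 0.20 ± 0.31 (SD, n = 3). In the CXXC and DNA methylation list the histone methyltransferase KMT2B was lower by -0.70 in UT7-5.3, and the DNA demethylase TET1 was higher by 0.54 in MV4-11. The hypoxia genes P4HA1, ALDOC, BNIP3 and NDRG1 had mean differences of 0.19, 0.15, 0.15 and -0.13. Fibroblast and epithelial markers had a mean difference of -0.04, and cytosolic ribosomal proteins one of 0.02.

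**Figure D2:**
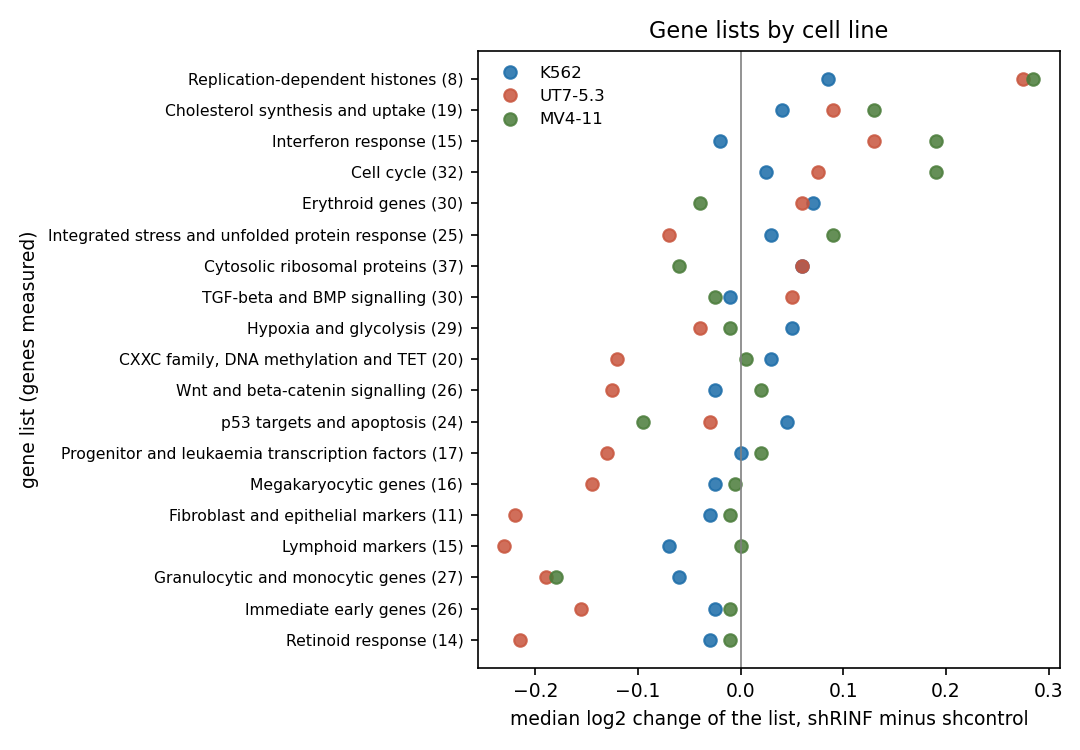
Median log2 change of each of the 19 gene lists on the x axis, with a point per cell line and the number of genes measured in parentheses after each list name on the y axis. The histone list lay at 0.09 in K562, 0.28 in UT7-5.3 and 0.29 in MV4-11, and the retinoid list at -0.03, -0.22 and -0.01.

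Within each line, with 1 array per condition and no test, the number of genes that differed 2-fold or more was 0 in K562, 27 in UT7-5.3 and 39 in MV4-11. The SD of the differences over all genes was 0.103 in K562, 0.259 in UT7-5.3 and 0.179 in MV4-11. At 1.5-fold or more, 4 genes were higher and 4 lower in K562, 241 higher and 74 lower in UT7-5.3, and 113 higher and 97 lower in MV4-11. The largest differences of each line are named below as values, without a replicate check.

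In K562 the highest were the metallothionein gene MT1G, at 0.69, FCER1G, the gamma chain of Fc receptors, at 0.67, HBD at 0.65, the spliceosomal RNA RNU5A-1 at 0.60 and LOC100289361 at 0.56. Their control values were 5.95, 4.62, 5.99, 7.30 and 6.40 in that order, so MT1G, FCER1G and HBD were of low signal too. The lowest were IGHD2-15 at -0.72, MIR181B1 at -0.64, KRTAP10-5 at -0.61, MIR553 at -0.59 and MIR3975 at -0.58, all of them low-signal features with control values of 5.83 or less.

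In UT7-5.3, 22 genes were 2-fold higher and 5 lower, or 34 and 5 after cyclic loess. The counts were 16 and 7 when a trend with mean level, gene length and chromosome, found after the data were examined, was removed. Several of the 22 were SNORD113 and SNORD114 features, which are alike in sequence, so the 22 are not independent. EPSTI1, an interferon-inducible gene, went from 6.36 to 7.86, and NTS, which encodes the neuropeptide neurotensin, was higher by 1.46. The small nucleolar RNA feature SNORD114-16 went from 6.12 to 7.52, and SNORD113-9 and SNORD113-1 were higher by 1.39 and 1.33. LINC01001 was lower by -1.13, the histone methyltransferase gene KMT2D by -1.04, SNORA2A by -1.03, POLR2A, the largest subunit of RNA polymerase II, by -1.03 and LINC01000 by -1.03. KMT2D and POLR2A differed by 0.03 or less in the other lines.

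In MV4-11, 23 genes were 2-fold higher and 16 lower. The laminin receptor integrin ITGA6 was higher by 2.16, the malic enzyme gene ME1 by 2.13, the metallothionein MT2A by 1.91, SHISA2 by 1.78 and NCKAP1, a subunit of the WAVE actin regulator, by 1.67. NCKAP1 lay near the floor in the control, at 4.18, so its difference is at best a lower bound. FGL2, a fibrinogen-like protein of macrophages and T cells, was lower by -2.68, going from 8.52 to 5.84. NCF1C, a pseudogene of a NADPH oxidase subunit, was lower by -1.42, the dendritic cell lectin CD209 by -1.37, MS4A6A by -1.29 and DHRS9 by -1.28. The array cannot fully separate NCF1C from its near-identical relatives. None of these 10 genes differed by more than 0.36 in K562 or UT7-5.3, where FGL2 and DHRS9 lay near the floor.

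**Figure D3:**
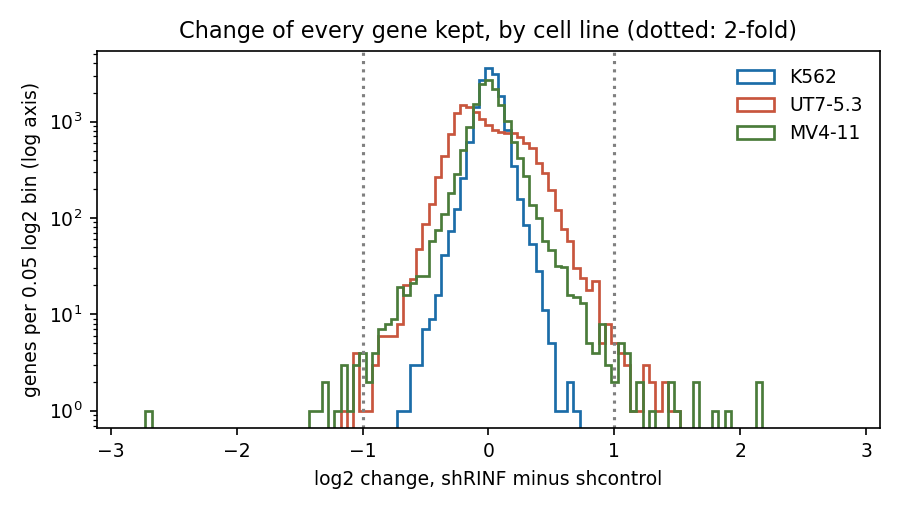
Number of genes on a log axis (y) in each 0.05-wide bin of log2 change, shRINF minus shcontrol (x), for the 3 cell lines, with dotted lines at a 2-fold change. The curve for UT7-5.3 is the widest (SD 0.259), the one for K562 the narrowest (SD 0.103), and MV4-11 reaches -2.68.

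Agreement between lines was examined gene by gene, and the lines share no array. No gene differed 1.5-fold or more in the same direction in all 3 lines, and none did so in the other sign patterns. At 1.2-fold, 16 genes did, 9 higher and 7 lower, where independent lists of that size would share 2.74. The patterns with MV4-11, UT7-5.3 or K562 in the opposite direction held 9, 10 and 8 genes. At 1.5-fold, HBD was higher in K562 and UT7-5.3, and MT1G in K562 and MV4-11. DYNLRB1, H2BC3, MARCKS and SELENOP were higher in UT7-5.3 and MV4-11, and CXXC5 and HLA-DRB6 were lower in both. Independent lists of these sizes would share 1.78 higher and 0.468 lower genes in UT7-5.3 and MV4-11. For higher genes they would share 0.0629 in K562 and UT7-5.3, and 0.0295 in K562 and MV4-11. H2BC3 lay near the floor in the MV4-11 control, at 3.80, so that its value there says little. MARCKS, an actin-binding substrate of protein kinase C, was higher by 0.86 and 0.76, and SELENOP, a secreted selenium transport protein, by 0.60 and 0.97. RNASE6 was higher by 0.69 in UT7-5.3 and lower by -0.64 in MV4-11. Across genes, which are not independent replicates, the differences correlated at r = 0.145 (rho = 0.171) between K562 and UT7-5.3, 0.0253 (0.0239) between K562 and MV4-11, and 0.104 (0.133) between UT7-5.3 and MV4-11. With the trend with mean level, gene length and chromosome removed, r was 0.118, 0.00856 and 0.0740 in that order.

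The lines themselves were compared with 2 arrays each, which shows what kind of cell each knockdown was made in. The 2 arrays of a line are a knockdown and a control, and not replicate cultures. The spread in the tests below is thus how the shRNA difference varied between lines. K562 and UT7-5.3 differed in 1508 genes at 2-fold or more and a limma adjusted p under 0.05, K562 and MV4-11 in 2317, and UT7-5.3 and MV4-11 in 2082. The genes below were picked for the widest range between lines in their lists, and whole lists were not tested between lines. RHAG, an erythrocyte membrane protein, had mean log2 values of 11.47, 10.36 and 4.32 in K562, UT7-5.3 and MV4-11, and the embryonic globin gene HBZ 12.33, 11.70 and 6.40. The erythroid transcription factor GATA1 lay at 10.42, 9.82 and 5.78. In MV4-11 the granule proteases CTSG, ELANE and PRTN3 lay at 11.31, 11.34 and 11.34, against 5.47 to 6.39 in the other lines. The receptor tyrosine kinase FLT3 lay at 9.75 in MV4-11, against 3.41 in K562 and 3.44 in UT7-5.3. The progenitor antigen CD34 and the stem cell factor receptor KIT were highest in UT7-5.3, at 8.63 and 8.62, and lay at 4.71 or less in the other lines. GP6, the platelet collagen receptor, was at 8.80 in UT7-5.3, 8.07 in K562 and 5.78 in MV4-11, and PLEK at 6.89, 4.29 and 8.88. CD4, which monocytes also express, was highest in MV4-11 at 8.86, and the epithelial antigen EPCAM in K562 at 7.71. CXXC5 differed little, with means of 8.18 in K562, 8.09 in UT7-5.3 and 8.27 in MV4-11 (limma adjusted p = 0.604, 0.556 and 0.213 for K562 against UT7-5.3, K562 against MV4-11 and UT7-5.3 against MV4-11).

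**Figure D4:**
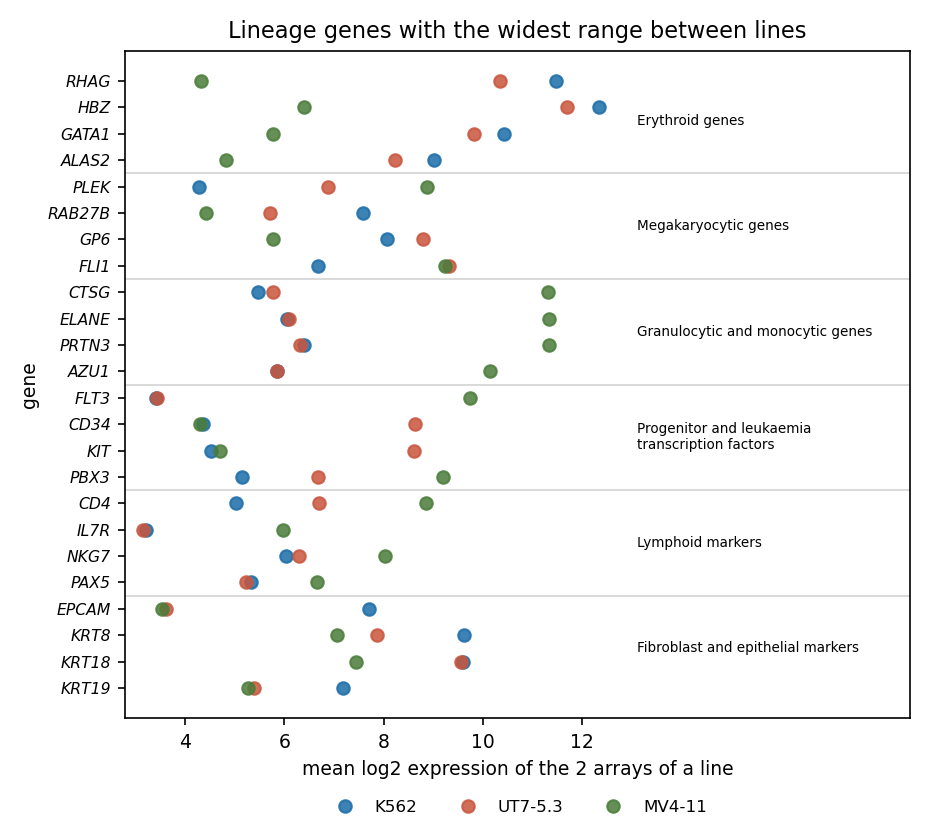
Mean log2 expression of the 2 arrays of each line (x) for the 24 lineage genes (y) with the widest range between lines, 4 per list. RHAG, HBZ, GATA1 and ALAS2 were low in MV4-11 alone, and CTSG, ELANE, PRTN3, AZU1 and FLT3 were high in MV4-11 alone.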

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

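RNASE6, a secreted antimicrobial ribonuclease, was flagged because its direction differed between lines. It was higher with shRINF by 0.69 in UT7-5.3 and lower by -0.64 in MV4-11, a gap of 1.33 between the lines, and differed by 0.08 in K562. It was the 1 gene kept that differed 1.5-fold or more in opposite directions, and the difference was not tested, since each line had 1 array per condition. At 1.5-fold, 241 genes were higher and 74 lower in UT7-5.3, and 113 and 97 in MV4-11. With lists of that size, 1 such gene may be met by chance.

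Features without a single gene symbol were left out of the gene comparisons. They were part of the alternative that tested each feature singly, in which no feature passed (smallest limma adjusted p = 0.283). Among 15730 distinct ones at log2 5 or more on at least 2 arrays, 60 differed 1.2-fold or more in the same direction in all 3 lines, 42 higher and 18 lower. The patterns with MV4-11, UT7-5.3 or K562 in the opposite direction held 34, 30 and 31 features. At 1.5-fold, 2 features did so, and the highest of the other patterns also held 2. The features stay unnamed here.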

How the results depend on the processing

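The trend removal and the protein-coding set were chosen after the data were seen. Of the alternatives for the mean difference of a named gene, 1308 kept direction and side of the threshold, 9 passed it and 9 reversed. For single lists 201 kept both, 24 lost the call, 2 gained one and 1 reversed. For the largest differences in a line, 216 kept direction and moved by less than the SD of that line's differences, and 1 did not. It was SNORD113-1 in UT7-5.3, at 0.943 with the trend removed, against 1.33. For counts 85 stayed within 1.5 times and 17 did not.

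The count of genes past the threshold was 0 in each direction and stayed there under the filters, the mean of features, features tested singly, the normalizations, the intensity trend and the trend removal. It became 1 higher (DYNLRB1) with protein-coding genes alone, where both the number of genes and the prior differ, 1 higher at an adjusted p under 0.1, and 1 higher and 1 lower (CXXC5) with robust eBayes. Leaving out a line gave 0 to 41 higher and 0 to 11 lower, the highest of both without MV4-11. Without the cell line as a block, which drops the pairing, 0 genes were higher and 0 lower. CXXC5 stayed between -0.65 and -0.54 over 14 alternatives, with limma adjusted p from 0.0208 to 1. It was -0.58 and past the threshold with robust eBayes, and -0.65 to -0.54 when a line was left out, past it without MV4-11 alone. DYNLRB1 had adjusted p from 6.27e-04 to 1. The prior degrees of freedom, on which these p-values lean, ranged from 3.35 (cyclic loess) to 12.7 (protein-coding genes) over filters and normalizations with all 3 lines, and were infinite without MV4-11.

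At 1.5-fold in place of 2-fold, 8 genes differed in K562, 315 in UT7-5.3 and 210 in MV4-11. At 1.2-fold in place of 1.5-fold, 16 genes agreed in 3 lines. With an estimated correlation 0 lists were higher and 0 lower. Leaving out a line gave 2 to 4 lists higher and 2 to 4 lower. With no fold minimum the lines differed in 6371, 7736 and 7413 genes, by construction more than at 2-fold.

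Over the 3 leave-outs CTSG lay between -0.095 and 0.58, S100A9 between -0.505 and 0.12, KIT between -0.025 and 0.315, and IL7R between -0.59 and 0.025, each reversed without MV4-11. CD34 lay between -0.285 and 0.005, CD3D between -0.02 and 0.30, IFI44 between -0.045 and 0.345, SLC7A11 between -0.065 and 0.41, and KMT2B between -0.335 and 0.03, each reversed without UT7-5.3. None of these 9 genes had passed, and the direction of each mean rested on the line left out. After cyclic loess the ribosomal protein list had a mean of -0.034 in place of 0.02 at camera's preset correlation (adjusted p = 0.0116, range 0.0116 to 0.932; 0.902 with an estimated correlation on the values as deposited), and the cause was not tested. Other normalizations moved the median difference of all genes by under 0.1 in every line. Without detection calls, features near the floor of the array could not be told from background.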

Other observations

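Metallothionein genes, which encode small metal-binding proteins, were singled out after their values were seen. In MV4-11 all 7 protein-coding members kept were higher with shRINF, with a median of 1.07, and 4 were 2-fold higher. MT2A was higher by 1.91, MT1G by 1.43, MT1H by 1.28 and MT1X by 1.07. Their median was 0.20 in K562. In UT7-5.3 it was -0.12, and 0.02 after cyclic loess, so that no direction held there. TGFB2, a TGF-beta ligand, was higher by 1.45 in MV4-11 and the protease gene PRSS12 by 1.52. IL1B, which encodes interleukin 1 beta, was lower by -1.01, F3 (tissue factor) was lower by -1.09, and the fractalkine receptor CX3CR1 went from 7.86 to 6.86. In K562 and UT7-5.3 the globin genes HBD and HBB and the chaperone gene AHSP, picked after their values were seen, were higher, with a median of 0.30 and 0.59. Of the other globin genes kept, HBZ differed by 0.02 in K562, 0.37 in UT7-5.3 and 0.24 in MV4-11, HBM by -0.14, 0.19 and -0.30, and HBQ1 by 0.08, 0.01 and -0.10. HBD, HBB and AHSP lay near the floor in MV4-11, at 3.91, 4.15 and 3.45 in the control, so that their values there say little.

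The patterns below, and the tests of them, were chosen after the data had been seen, apart from cyclic loess, which had been chosen before. What each explanation would give was written before its test for the splits, the trend and cyclic loess, but after some values were seen for MV4-11 and for the other small nucleolar RNAs.

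The UT7-5.3 differences were wider than those of the other lines and followed properties of the genes. Their median ranged from -0.16 to 0.13 over 10 bins of mean level, highest in the top bin, and among protein-coding genes from -0.18 on chromosome 22 to 0.18 on chromosome 4. Mean level, gene length and chromosome accounted for 19.9% of their variance, against 5.16% in K562 and 1.76% in MV4-11. With that trend removed their SD was 0.232, down from 0.259 but above the 0.178 of MV4-11, and after cyclic loess it was 0.248, so neither accounts for the whole width. A difference in RNA quality or base composition between these 2 arrays and an effect of the knockdown stay open, since the line had 1 array per condition.

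In MV4-11 the granule protease genes and other myeloid genes moved apart. K562 or UT7-5.3 cells in the shRINF sample are argued against as the source of most of the higher genes, since 18 of the 23 genes 2-fold higher lay above every array of the other lines. The 6 genes abundant in both other lines and low in the MV4-11 control had a median of 0.17, against 2.25 if ME1 came from such cells at the share of 8.05% it would need. The 5 primary granule genes of the myeloid list (MPO, ELANE, AZU1, PRTN3, CTSG) had a median of 0.87, all 5 higher, or 4 after a further quantile normalization, and the other 22 a median of -0.26, 17 of them lower. A shift towards a less mature state may underlie this, as a hypothesis that cannot be told apart from drift between 2 cultures, because the sets were drawn after some values were seen and rest on 1 pair of arrays.

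All 29 SNORD113 and SNORD114 features, small nucleolar RNAs of an imprinted cluster on chromosome 14, were higher in UT7-5.3, 21 of them 1.5-fold or more, with a median of 0.83. A general rise of such RNAs is argued against, since 127 other snoRNA features had a median of 0.05 there. With the trend removed 28 of the 29 were higher and the median was 0.60, so the trend accounts for part at most, and how much cannot be told apart because its chromosome term includes these features. In K562 and MV4-11 the features lay near the floor, with a median control level of 2.90 in both, and MEG3, a gene of the same cluster, differed by -0.12 in UT7-5.3. Members of the family are alike in sequence, so the 29 are not independent, and a local change in the cluster may be the source, as a hypothesis.

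In limma's comparison across lines, 3 of the 10 splits of the 6 arrays gave 981 genes or more at an unadjusted p under 0.05. These include the real split, which gave 981. The others were 1 contrast of UT7-5.3 and its mirror image, which gave the same 5368. For the lists at the preset correlation, 3 of the 10 splits gave 8 or more, again with the real split, at 8, among them. The others were 1 contrast of MV4-11 and its mirror image, with 9. With 10 splits the share is never under 0.1, too large to decide. The 3 other splits that part all pairs gave 526, 348 and 621 genes and 2, 0 and 6 lists. The real split was thus the highest of those that part all pairs on both counts, but so few splits cannot decide. The splits that part a single pair differ, in that they set 1 line's difference against the spread of the others. Those that part UT7-5.3 gave the 5368, which points to the structure of that pair, and those that part MV4-11 gave the 9 lists.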
